A study of Folsomia candida with 64 samples.

How the data were processed

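The samples were 23-day-old springtails kept for 2 days at 20 °C in jars of field soil, with about 30 animals per jar, per the labels' protocols. The labels' protocols give 30 g of soil per jar, and the series text gives 25 g. For each sample 500 ng of RNA was labelled with Cy3 or Cy5 and hybridised to an Agilent array, per the labels. Each array carried 5069 probes with 3 spots each and a Cy3 and a Cy5 sample, laid out as an interwoven loop. There were 8 arrays on each of 4 slides, and every slide held 1 sample of each of the 16 groups, so that the replicate number of a sample was also its slide. The labels mark 41 of the 64 samples as used in the submitters' analysis.

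The scanner files give the spot intensity of each channel, as mean signal, local background and processed signal on a linear scale, and were written by Agilent Feature Extraction 9.5.1.1, per the file headers. The deposited value table holds log2 values per spot and sample, which were averaged per probe here. The submitters' processing notes name limma, and its role, settings and version are not given in the sources used here. Its 64 columns all matched a sample by name, and 0 columns were left unused. Values ran from 4.19 to 20.91 and column medians from 7.57 to 8.99. Set against the log2 intensity of the sample of its own label, a column correlated at r = 0.937 to 0.986 over spots. The level of a probe is similar in most samples. The scale was therefore that of log2 intensity with the same direction, the probes were not centred, and how the table was normalized between arrays stays unknown.

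The table and the scanner files disagreed on which array belongs to which sample. All 32 table arrays matched the scanner array at the same position of the next slide, with a lowest r of 0.966 over probes. The scanner files were kept as the main source. The pairing of the table was applied to the scanner data as an alternative, and the pairing of the scanner files to the table as another, both chosen after the data were seen. All 4 shifts of the slides were compared, for the scanner data and for the table.

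Background was corrected by normexp with an offset of 50 on mean signal and median background. Normalization used loess within arrays and Aquantile between arrays, and the channels were then taken as separate log2 values. Spots marked as outliers were left out before the spots of a probe were averaged, and for 123 probe-by-sample values in which every spot was marked, all spots were averaged. The files held 0 control spots. A probe was tested if it was well above background in at least 5 of the samples of the fit, which kept 4199. No sample pair had identical values (0 pairs), and the highest correlation between samples was r = 0.9949.

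Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes, on 41 samples. Copper level, pH level and dye were factors, and the array was a random block through duplicateCorrelation (correlation 0.299 in the additive model, 0.37 with the interaction and 0.273 with slopes). The additive model gave the F tests over the levels, with 3 degrees of freedom, and the contrasts of copper 4 against 1 and pH D against A. The interaction F test covered 9 terms. Slopes per copper level, with the levels taken as equally spaced, were fitted within each pH. Values were adjusted by Benjamini-Hochberg over probes at a threshold of 0.05, and intervals are at 95%. Groups that kept 1 used sample took their spread from the other groups. Error bars in the text after fitted differences are standard errors, and those after group means are standard deviations.

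Of 20 gene lists written from protein names before the data were examined, 15 had at least 5 tested genes and were tested. They cover stress, detoxification, ion regulation, digestion, cuticle, lipid, ribosome, mitochondrion, muscle, proteasome and bacterial genes. Those on copper handling, yolk, immunity, beta-lactam synthesis and the cell cycle had too few. A gene was represented by its brightest probe. Lists were tested with limma's camera with a preset correlation of 0.01, with camera with an estimated correlation, and with fry, and adjusted over the lists. After the first list tests had been seen, 5 names that had matched by their letters alone were removed, and the same lists passed. The names counted as uninformative were also widened after the named genes had first been listed. The array number limits the precision of every value.

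Gene names are those of the best protein match written in the files. Of the probes, 45.8% had a match and 21.3% an informative name. The RefSeq gene table of the species held 0 of the 6302 array identifiers. The rule for named genes was set before the data were examined. For copper and for pH it takes the probes with a name that pass both the F test and the end contrast, or, as none passed, the 10 with the lowest p of the F test. It adds up to 4 members of each list by the lowest F-test p and 6 genes each for the interaction and the slope difference. How many list members to print was decided after their values were seen. Fcc01630, the cellulase Fcc05266 and the probes and genes in the closing part on gene lists and variable genes fall outside that rule and were chosen after their values were seen.

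The fits were tested on simulated data with the real design, with 50 of 4199 probes changed at each size. The noise of each probe was drawn on its own, so genes did not vary together as they do in real samples. The recovered shares and list calls therefore do not carry over to genes that vary together. For copper 4 against 1, limma recovered 24% of the changes of 0.25 log2 units, 70% at 0.5, 98% at 1 and 100% at 2. For pH D against A it recovered 22%, 66%, 94% and 100%. For the copper F test the shares were 22%, 66%, 96% and 98%, and for the pH F test 40%, 74%, 98% and 100%. The interaction F test recovered 0%, 0%, 12% and 68%, and the slope difference 0%, 6%, 34% and 80%. The simulated interaction change was set in copper 4 and pH D alone, a group with 1 used sample. For the slopes at pH A, B, C and D, 66%, 74%, 82% and 58% of probes with a change of 1 from copper level 1 to 4 were recovered. Of 3 lists moved by 0.3, camera called 3 for copper and 3 for pH, with 1 and 0 other lists called.

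Slide, dye and scanning day were tested as batches. Alternatives fixed before the data were examined covered the samples, array weights, slide as a block, background correction, normalization, the filter on dim probes, the dye term, the array block, the variance model, the coding of the levels, the value table and leaving out each sample in turn. A further 4 alternatives were added after the data were seen, namely the data moved by 1 slide, the same with all 64 samples, the fit without the groups of 1 used sample, and the value table paired as the scanner files. Used and not used samples were compared with a two-sided permutation test with 100000 resamples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.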

Results

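Transcript levels were measured in whole springtails of the species Folsomia candida, a small soil arthropod used in tests of soil toxicity, after 2 days in agricultural field soil. The soil had 4 copper levels, named 1 (low) to 4 (high), and 4 pH levels, named A (low) to D (high), which made 16 soil groups with 4 samples each. The labels call the samples of a group biological replicates, each with the RNA of about 30 animals from its own jar. The copper concentrations and pH values behind the level names are not given in the sources used here. The 64 samples were hybridised in pairs, with a Cy3-labelled and a Cy5-labelled sample on each of 32 arrays, and each of the 4 slides held 1 sample of every group. According to the labels, the submitters used 41 of the samples in their analysis and left out 23, with no reason given. The comparisons below rest on the 41 used samples, of which 13, 8, 11 and 9 had copper levels 1, 2, 3 and 4, and 9, 11, 12 and 9 had pH levels A, B, C and D. Of the 16 groups, 5 kept 1 used sample.

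Between 69% and 83.6% of the spots of a sample were well above background, with a median of 78.3%. The median spot intensity of a sample lay between 109 and 337 in the Cy3 channel and between 391 and 1310 in the Cy5 channel. Used and not used samples differed by less than the spread between samples in these measures. The share of spots well above background was 77.3% ± 3.44 (SD, n = 41) in used and 77.8% ± 4.1 (SD, n = 23) in not used samples (two-sided permutation test, p = 0.632, adjusted p = 0.955 over the measures compared). The log2 median intensity was 8.57 ± 1.04 and 8.45 ± 0.983 (permutation p = 0.646, adjusted p = 0.955), and 291 ± 20.1 spots were marked as outliers in both sets (permutation p = 0.955, adjusted p = 0.955). The array held 5069 probes, and 2321 of them carried the best protein match of their transcript in the files. An informative protein name stood with 1081 probes, often from a distant species, so a name below is that of the best match. None of the 6302 array identifiers occurred in the RefSeq gene table of this species (0 matched), so no genome position is given. Of the probes, 4199 were well above background in enough samples to be tested, and 878 of those had a protein name.

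The deposited value table and the scanner files paired samples with arrays in different ways, and this bears on every comparison below. When the log2 ratio of Cy5 over Cy3 was compared over probes, all 32 arrays of the value table matched the scanner array at the same position on the next slide. The lowest correlation with that array was r = 0.966 across probes, and the median correlation of a table array with the scanner array of its own label was r = 0.0251. Genes are not independent replicates in such a correlation. The files do not show which pairing is right. The values below follow the scanner files, which were chosen as the source before the data were examined, and outcomes with the value table's own pairing are given for the copper, pH and interaction comparisons. Samples of the same group were not more alike than samples of different groups in either pairing. The mean correlation of samples of 1 group minus that of different groups was -0.0149 with the scanner files' pairing (permutation p = 0.589, adjusted p = 0.766) and -0.0483 with the data moved by 1 slide to the table's pairing (permutation p = 0.0761, adjusted p = 0.304 over the 4 slide shifts compared).

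**Figure D1:**
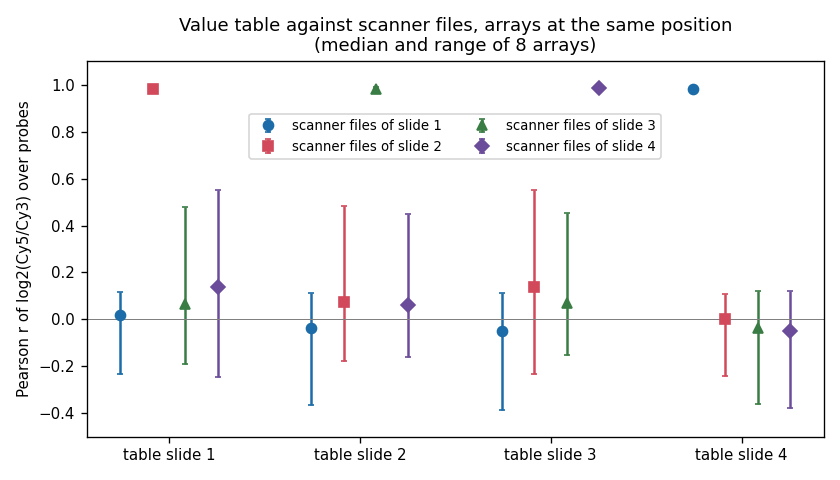
Pearson correlation across probes of the log2 Cy5 over Cy3 ratio between each slide of the value table and each slide of the scanner files, for arrays at the same position; points are medians and bars ranges of 8 arrays. Table slide 1 matches the scanner files of slide 2 with a median r of 0.983, and every table slide matches the next scanner slide.

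The copper comparison asked which transcripts differed between copper levels, with soil pH as a term of the additive model. The used samples were uneven over the groups. At pH A to D, copper level 1 kept 1, 4, 4 and 4 of them, and level 4 kept 3, 1, 4 and 1. The fitted differences therefore assume the same copper effect at every pH. The list on metallothionein and copper handling had 3 tested genes, none of them a metallothionein match. They differed little between copper level 4 and level 1. The fitted log2 difference was 0.06 ± 0.08 (SE) for a laccase, a multicopper oxidase (Fcc02070), 0.00 ± 0.09 for a copper transporter of solute carrier family 31, which carries copper into cells (Fcc04079), and -0.07 ± 0.07 for a secreted ferritin subunit, an iron storage protein (Fcc04961). None of these 3 genes passed the threshold, over all probes or adjusted over the list alone (lowest adjusted p = 0.652), and the sign for the transporter and the laccase turned with all 64 samples. For stress genes the difference was 0.05 ± 0.10 for heat shock protein 70 (Fcc02719), 0.06 ± 0.14 for a 23-kDa heat shock protein (Fcc01918), 0.10 ± 0.08 for soluble superoxide dismutase (Fcc00755) and -0.06 ± 0.24 for a thioredoxin (Fcc04514), and these signs turned in some settings. The 23-kDa protein was well above background in 7 of the 41 samples, 1 of them at copper level 1, and the superoxide dismutase in 18, with 3 of 13 at that level. The 8 heat shock proteins and chaperones had a mean difference of 0.05 with 6 positive, and the 11 genes of oxidative stress defence a mean of 0.03 with 7 positive (limma's camera, adjusted p = 0.49 for both lists).

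The cytochrome P450 genes, oxidases of foreign compounds, hormones and lipids, formed the list that passed between the copper levels. All 9 measured genes lay higher at copper level 4 than at level 1, by 0.17 log2 units on average (camera with a preset correlation, adjusted p = 0.0121), and the call was lost with adjusted p = 0.508 with an estimated correlation. Examples were Fcc01651, closest to CYP6N4v1 of a mosquito, at 0.27 ± 0.10 (SE), and Fcc02595, closest to the cockroach CYP15A1, at 0.27 ± 0.21. Another was Fcc00266 at 0.34 ± 0.24, with 0.23 without replicate 1 of copper 4 and pH C and 0.52 without replicate 2. With equal weights for the 16 groups Fcc00266 was at -0.01, and with all 64 samples Fcc02595 was at -0.06. Fcc01651 was well above background in 23 of the 41 samples, 6 of 13 at copper level 1 and 6 of 9 at level 4. None of the 9 passed over all probes and 0 passed adjusted over the list alone, with a lowest adjusted p of 0.101. The fry test of a common direction gave an adjusted p of 0.759. The list's call was lost in 4 of the 41 fits that left out 1 sample, where the lowest mean was 0.111 and the highest adjusted p = 0.158, with the scanner software's processed signals (adjusted p = 0.065) and with the filter at 75% of samples (adjusted p = 0.0587). It was also lost with all 64 samples, where its mean was 0.029 (adjusted p = 0.701), and its mean was -0.148 in the value table (adjusted p = 0.476).

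Of the other 14 lists, digestive proteases came closest, with a mean of 0.14 and 7 of 9 genes positive (adjusted p = 0.257). The enzymes of phase II detoxification, which conjugate foreign compounds, had a mean of 0.08 with 11 of 14 positive (adjusted p = 0.261). The means were 0.10 for carbohydrate digestion, 0.10 for muscle structure, 0.08 for pH and ion regulation, 0.05 for bacterial matches, 0.04 for cuticle and chitin, 0.02 for lipid metabolism, 0.02 for cytosolic ribosomal proteins, 0.00 for mitochondrial respiration, 0.00 for proteasome and ubiquitin and -0.02 for ABC and multidrug transporters. For transporters and lipid metabolism the list mean understates the median, at 0.02 and 0.08, and the transporter test pointed up.

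No single probe passed between copper levels at an adjusted p of 0.05. The moderated F test over the copper levels in limma called 0 of 4199 probes, with 50 at an unadjusted p under 0.05 and a lowest adjusted p of 1. The contrast of level 4 against level 1 called 0, with 85 at an unadjusted p under 0.05, of which 38 were higher and 47 lower at level 4 (lowest adjusted p = 0.999). The 95% interval of a probe's difference reached 0.231 log2 units to either side at the median probe. Among named genes with the lowest F-test p, an acetyl-CoA carboxylase domain protein of fatty acid synthesis (Fcc04988) was at 7.16 ± 0.31 (SD, n = 9) at copper level 4 and 6.94 ± 0.16 (SD, n = 13) at level 1, a fitted difference of 0.28 ± 0.11 (SE). A zinc finger protein (Fcc04248) had a difference of 0.23 ± 0.14 and a myosin light chain (Fcc00218) one of 0.14 ± 0.09. A putative cyclase (Fcc03343) lay at -0.15 ± 0.08, a protein phosphatase (Fcc06090) at -0.16 ± 0.09, a protein like the mite group 2 allergen (Fcc04297) at -0.22 ± 0.23, an RNA polymerase II subunit (Fcc02021) at -0.10 ± 0.07 and a GMP synthetase match (Fcc05933) at -0.05 ± 0.06. A syntaxin 5 match (Fcc03142) lay at 0.08 ± 0.08, and each of these 9 genes had an adjusted p of 0.999. Leaving out 1 sample moved Fcc04248 to 0.14, Fcc04297 to between -0.31 and -0.14, Fcc05933 to between -0.08 and -0.02 and Fcc03142 to between 0.02 and 0.12. With the table's own pairing, the value table gave 3 probes in the copper F test, and none of them passed with the scanner files. In that pairing 4 lists passed and lay lower at copper level 4, namely ribosomal proteins (mean -0.24, 26 of 27 genes lower, adjusted p = 7.42e-06), carbohydrate digestion (-0.38, adjusted p = 0.0258), phase II detoxification (-0.18, adjusted p = 0.0347) and muscle structure (-0.23, adjusted p = 0.0374). With an estimated correlation the adjusted p = 0.604 for all 4 lists.

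**Figure D2:**
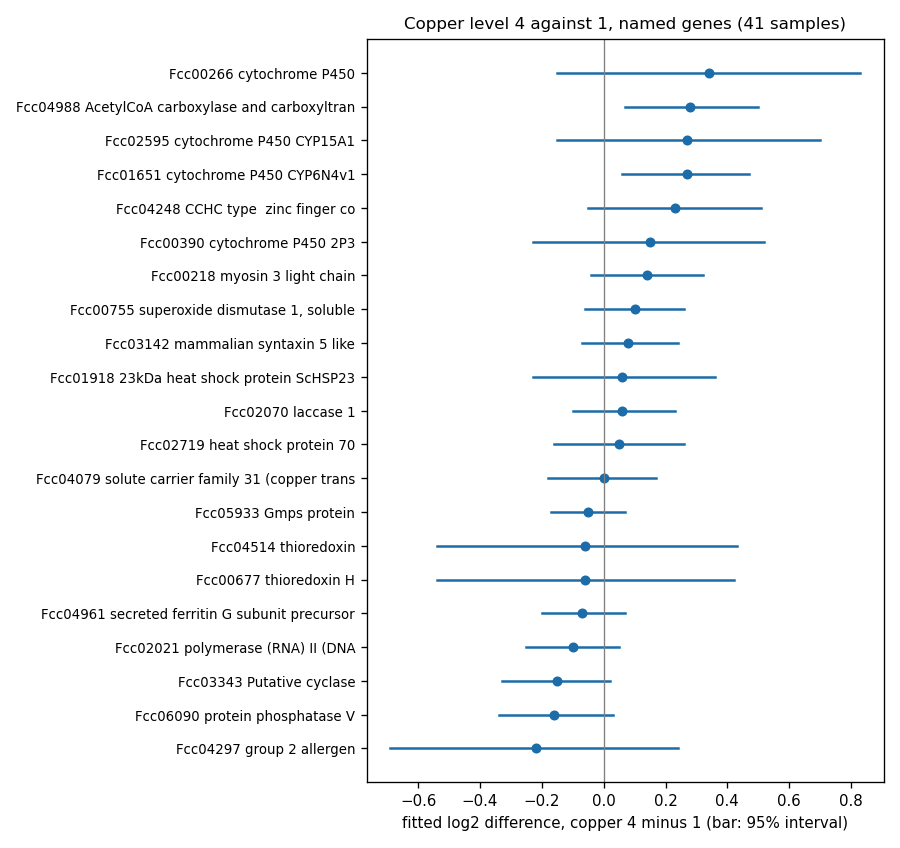
Fitted log2 difference between copper level 4 and level 1 for the named genes, with 95% intervals as bars, from 41 samples; the horizontal axis is in log2 units. The interval of the copper transporter Fcc04079 is centred on 0.00, and that of the cytochrome P450 Fcc01651 runs from 0.06 to 0.47.

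The pH comparison asked which transcripts differed between the least and most acidic soils, with copper as a term of the additive model. At copper levels 1 to 4, pH A kept 1, 2, 3 and 3 used samples, and pH D kept 4, 3, 1 and 1. The fitted differences therefore assume the same pH effect at every copper level. The lists of carbohydrate digestion, muscle, cytochrome P450 and ribosomal genes passed with a preset correlation between genes and not with an estimated one (adjusted p = 0.396 and 0.417), and no single probe passed. Apolipophorin, the carrier protein of lipids in insect blood (Fcc02219), was at 7.20 ± 0.33 (SD, n = 9) at pH D and 6.73 ± 0.23 (SD, n = 9) at pH A, with a fitted log2 difference of 0.57 ± 0.13 (SE). Acetyl-CoA carboxylase, which makes the first committed step of fatty acid synthesis (Fcc00050), was at 11.64 ± 0.39 (SD, n = 9) and 10.85 ± 0.46 (SD, n = 9), a difference of 0.97 ± 0.25 (SE). The alpha subunit of the sodium and potassium pump (Fcc04059) differed by 0.60 ± 0.16, and a calcium-transporting ATPase (Fcc06092) by 0.60 ± 0.19, which was 0.30 without replicate 2 of copper 2 and pH A. These 4 genes had an adjusted p of 0.237, so none passed over all probes, and each had the opposite or a smaller value in the value table with its own pairing, where apolipophorin was at -0.33 and acetyl-CoA carboxylase at -0.27.

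Carbohydrate digestion was the list with the most single genes past its own threshold. Its 7 genes were 0.31 log2 units higher at pH D on average, with 6 of 7 positive (camera with a preset correlation, adjusted p = 0.0386). With an estimated correlation the adjusted p = 0.396. Adjusted over the list alone, 3 genes passed, each with an adjusted p of 0.0111, and 0 passed over all probes. They were a maltase-glucoamylase match (Fcc00529) at 0.85 ± 0.26 (SE), a preamylase (Fcc02249) at 0.61 ± 0.20 and a second maltase-glucoamylase match (Fcc00152) at 0.57 ± 0.19, enzymes that break starch and maltose down to glucose. The exception was a xylanase (Fcc04469), an enzyme that cuts plant xylan, at -0.71 ± 0.33. Muscle genes lay higher as well. All 6 measured genes were positive with a mean of 0.27 (adjusted p = 0.0386), and adjusted p = 0.396 with an estimated correlation. Titin (Fcc05061) was at 0.64 ± 0.23 and passed over the list alone (adjusted p = 0.0499), and troponin C (Fcc04074) was at 0.41 ± 0.21. The myosin light chain (Fcc00218) was at 0.17 ± 0.09, or 0.07 without replicate 2 of copper 2 and pH A. With all 64 samples and array weights, titin was at -0.08 and the myosin light chain at -0.11, while troponin C kept its direction.

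The cytochrome P450 genes had a mean of 0.26 with 7 of 9 positive (adjusted p = 0.0386), and adjusted p = 0.396 with an estimated correlation. Fcc01651 was at 0.32 ± 0.10 (SE) and passed over the list alone (adjusted p = 0.0345), with 3 of 9 samples well above background at pH A and 6 of 9 at pH D. The others named for copper were Fcc02595 at 0.50 ± 0.22 and Fcc00266 at 0.55 ± 0.25. The cytosolic ribosomal proteins, parts of the machinery of protein synthesis, had the smallest mean of the lists that passed. Of 27 genes, 25 were positive with a mean of 0.15 (adjusted p = 0.00192), and adjusted p = 0.417 with an estimated correlation. The estimated correlation between the ribosomal genes was 0.37. Ribosomal protein L22e (Fcc05148) was at 0.41 ± 0.19, L44e (Fcc03365) at 0.19 ± 0.10 and L27 (Fcc00048) at 0.16 ± 0.10, and none of the 27 passed alone. Without replicate 2 of copper 2 and pH A, L22e was at 0.04 and L27 at 0.02. Among the 41 fits that left out 1 sample the ribosomal call was kept in all, while those of carbohydrate digestion and cytochrome P450 were lost in 5 each and that of muscle in 7. Without background subtraction or without the array block, 1 of the 4 lists passed, the ribosomal proteins, and without replicate 2 of copper 2 and pH A 7 lists passed. Of these 4 lists, the ribosomal proteins also passed with all 64 samples (mean 0.135, adjusted p = 4.46e-08), with adjusted p = 0.269 with an estimated correlation, and the other 3 did not. In the value table with its own pairing the ribosomal mean was -0.171 (adjusted p = 0.00667, and adjusted p = 0.669 with an estimated correlation), the opposite direction, and the means of the other 3 lists were negative there too. The fry test gave adjusted p values of 0.121 for ribosomal proteins and 0.062 for the other 3 lists.

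The remaining 11 lists did not pass between pH levels. Cuticle and chitin genes had the highest mean, 0.35 with 4 of 5 positive (adjusted p = 0.184), and an endochitinase (Fcc02522), which cuts chitin, was at 0.72 ± 0.23 (SE) and passed over the list alone (adjusted p = 0.0201). Digestive proteases had a mean of 0.21 with 7 of 9 positive (adjusted p = 0.177) and phase II detoxification a mean of 0.18 with 10 of 14 positive (adjusted p = 0.086). With slide as a block the phase II list passed (adjusted p = 0.0463, and adjusted p = 0.477 with an estimated correlation). In the value table with its own pairing it passed in the other direction, with a mean of -0.25 and 13 of 14 genes lower (adjusted p = 0.000932, and adjusted p = 0.669 with an estimated correlation). A trypsin (Fcc00353) was at 0.56 ± 0.24, and the glutathione transferases Fcc01480 and Fcc06274 at 0.49 ± 0.20 and 0.33 ± 0.14. Bacterial matches had a mean of 0.16 with 7 of 8 positive, oxidative stress defence 0.10, and heat shock proteins and chaperones 0.09. For lipid metabolism the mean of 0.09 and the median of -0.03 differed in sign, and apolipophorin passed over that list alone (adjusted p = 0.0013). The 8 genes of pH and ion regulation, the list closest to soil acidity, had a mean of 0.07 with 5 positive (adjusted p = 0.669), with an aquaporin water channel (Fcc00183) at -0.22 ± 0.09 and a vacuolar ATPase subunit (Fcc03280) at -0.02 ± 0.16. Mitochondrial respiration was at -0.04, proteasome and ubiquitin at -0.03, and ABC and multidrug transporters at -0.16. Of 3 yolk and reproduction genes, too few for a list test, vitellogenin (Fcc05618), the yolk precursor, was at 0.58 ± 0.23 and passed over the list alone (adjusted p = 0.0452).

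**Figure D3:**
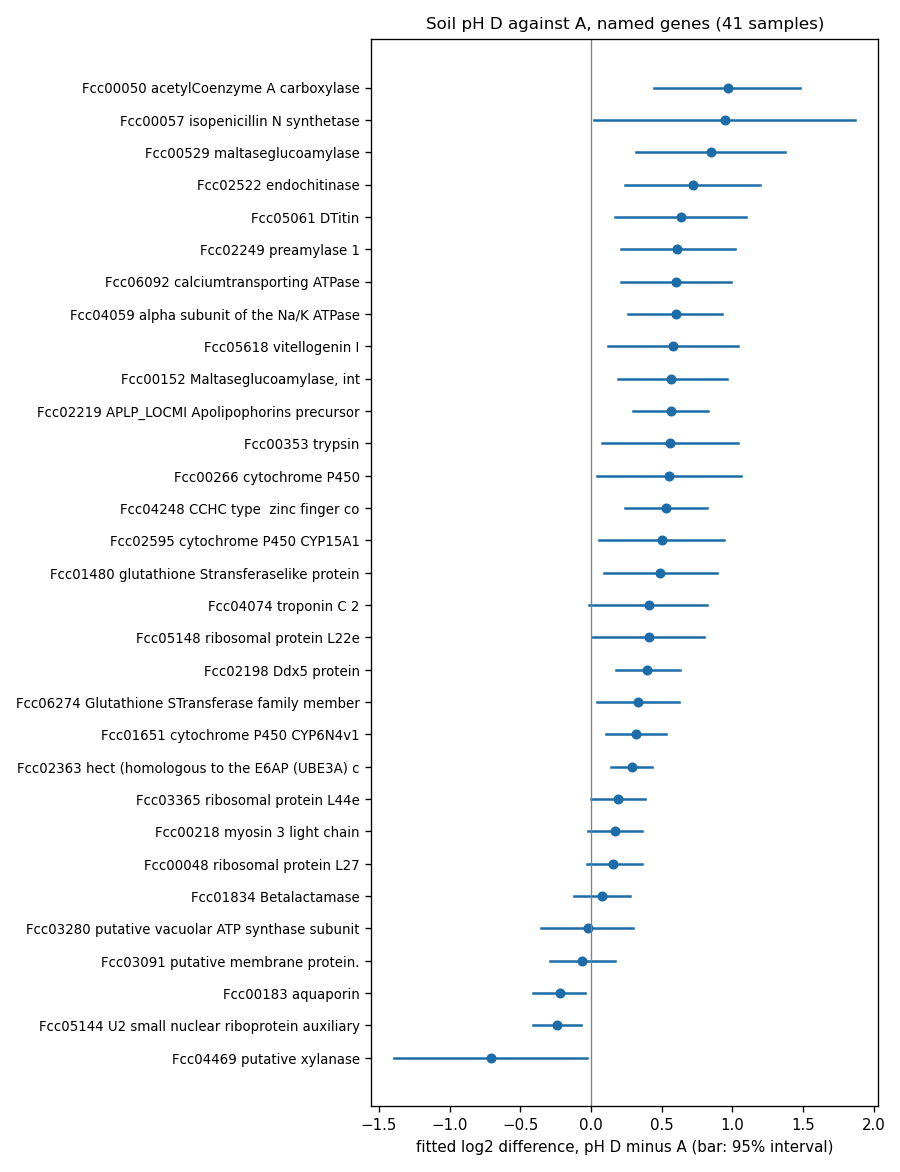
Fitted log2 difference between pH level D and level A for the named genes, with 95% intervals as bars, from 41 samples; the horizontal axis is in log2 units. The interval of apolipophorin (Fcc02219) runs from 0.30 to 0.83 and that of acetyl-CoA carboxylase (Fcc00050) from 0.45 to 1.48, and the xylanase Fcc04469 lies lowest at -0.71.

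Over all probes, limma's F test over the pH levels called 0 of 4199, with 220 at an unadjusted p under 0.05 (lowest adjusted p = 0.629). The contrast of pH D against A called 0 as well, with a lowest adjusted p of 0.237, although 687 probes (16.4%) had an unadjusted p under 0.05, of which 403 were higher and 284 lower at pH D. Further named genes near the top were an RNA helicase, Ddx5 (Fcc02198), at 0.40 ± 0.11 (SE), a HECT-type ubiquitin ligase (Fcc02363) at 0.29 ± 0.07, the zinc finger protein Fcc04248 at 0.53 ± 0.14 (0.30 without replicate 2 of copper 2 and pH A) and the splicing factor U2AF (Fcc05144) at -0.24 ± 0.08, each with an adjusted p of 0.237. A putative membrane protein (Fcc03091) was at -0.06 ± 0.11, with means of 12.82, 12.44, 12.56 and 12.79 at pH A to D.

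The version of the values decided whether single genes passed. When each column of the value table was given to the sample whose scanner array it matched, an alternative chosen after the data were seen, the same 41 samples gave 215 of 4199 probes between pH D and A, with 187 higher and 28 lower at pH D (lowest adjusted p = 0.0076). The table's own pairing gave 0, with 263 at an unadjusted p under 0.05. All 215 had the same direction in the fit of the scanner files, and 203 had an unadjusted p under 0.05 there. Both versions come from the same arrays and samples, so this likeness is no independent support. In that version apolipophorin was at 0.84 (adjusted p = 0.0129), acetyl-CoA carboxylase (Fcc00050) at 1.34 (adjusted p = 0.0129), the preamylase Fcc02249 at 1.00 (adjusted p = 0.0186) and vitellogenin Fcc05618 at 0.84 (adjusted p = 0.0361). The count depended on single samples. It was 0 without replicate 1 of copper 4 and pH C, 1 without replicate 1 of copper 3 and pH A, and 458 without replicate 1 of copper 2 and pH A, with a median of 174 over the 41 fits that left out 1 sample. With all 64 samples 0 probes passed and 718 had an unadjusted p under 0.05.

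**Figure D4:**
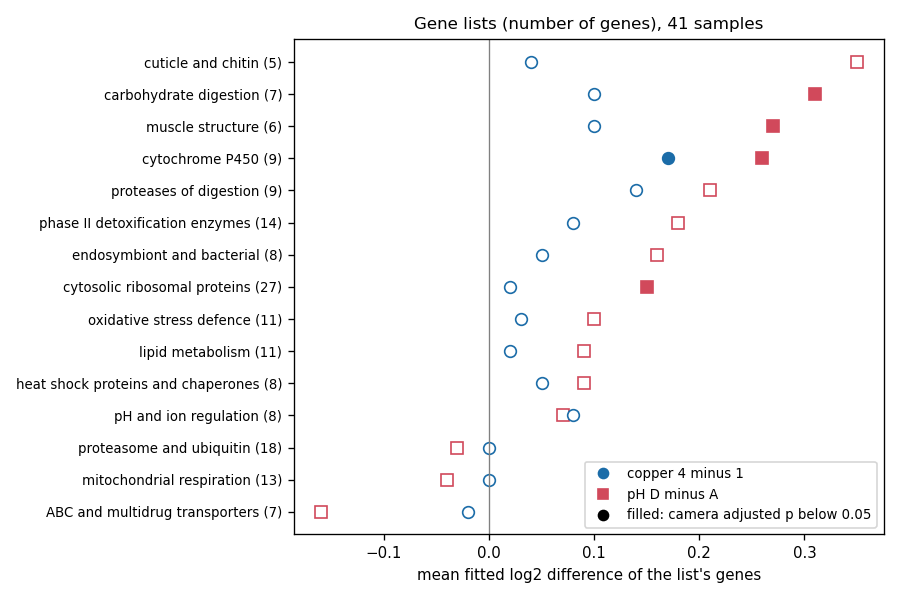
Mean fitted log2 difference of the genes of each list, for copper level 4 minus level 1 (circles) and pH level D minus level A (squares), from 41 samples; filled symbols passed the camera test with a preset correlation. The filled symbols are cytochrome P450 for copper at 0.17 and, for pH, carbohydrate digestion at 0.31, muscle structure at 0.27, cytochrome P450 at 0.26 and ribosomal proteins at 0.15. None of them passed with an estimated correlation between genes.

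The interaction asked whether the effect of copper depended on soil pH. With the used samples it gave a single transcript. Fcc01630, whose best match is a hypothetical protein of a slime mould, was the probe that passed the interaction F test (limma, 1 of 4199 probes, adjusted p = 0.000885, with 210 at an unadjusted p under 0.05). The probe was well above background in 28 of the 41 used samples, 5 of 9 at pH D. It was also the probe that passed the copper slope at pH D, where it was higher by 0.79 ± 0.14 log2 units per copper level (adjusted p = 0.0171). With slide as a block that slope was 0.76 and did not pass (adjusted p = 0.0517). Its slope at pH A was -0.24 ± 0.14, and the difference of the slopes was 1.02 ± 0.21. The value rested on 1 sample. Replicate 4 of copper 4 and pH D, the used sample of that group, had a log2 intensity of 9.88, while the other samples of the group, not used by the submitters, had 6.35, 6.46 and 6.57. Without that sample the slope at pH D was 0.11 and no probe passed either test. The number of probes in the interaction F test depended on other samples too, with 140 without replicate 1 of copper 2 and pH A, 9 without replicate 4 of copper 2 and pH D and 5 without replicate 4 of copper 1 and pH B. It was 0 with all 64 samples, with the scanner software's processed signals and with the filter at 75% of samples. In the value table with its own pairing 1 probe passed the interaction F test (adjusted p = 0.0161) and 0 the slope at pH D, where that of Fcc01630 was -0.04 and its slope difference -0.36.

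The slope of log2 intensity per copper level called 0 probes at pH A, B and C, with 133, 128 and 127 at an unadjusted p under 0.05, and 1 at pH D, with 51. The difference between the slopes at pH D and A called 0, with 106 at an unadjusted p under 0.05 and a lowest adjusted p of 0.08. Of the named genes near the top of the interaction test, 2 matched enzymes of antibiotic synthesis in moulds and bacteria. The synthetase of the tripeptide precursor of penicillin (Fcc00170) had slopes of -0.70 ± 0.25 (SE) at pH A and 0.40 ± 0.25 at pH D, and isopenicillin N synthetase (Fcc00057), the next enzyme of that pathway, -0.68 ± 0.29 and 0.38 ± 0.29. Their interaction adjusted p was 0.589 for both, so neither passed. Their slope differences were 0.36 and 0.14 without replicate 3 of copper 1 and pH A, the used sample of that group, and -0.21 and -0.05 in the value table with its own pairing. A methyl transferase (Fcc01758), well above background in 8 of the 41 samples, had a slope difference of 0.73 ± 0.24 (0.26 without that sample), an oxidoreductase (Fcc05644) of 0.49 ± 0.17, the membrane protein Fcc03091 of 0.29 ± 0.10 and a protein named pinball wizard (Fcc03386) of 0.26 ± 0.10. A retinoid-binding protein (Fcc01312) was at 0.22 ± 0.48, a chloride channel (Fcc04548) at 0.12 ± 0.12 and lipidosin (Fcc00031) at -0.08 ± 0.11. Without replicate 3 of copper 1 and pH A these 3 were at 0.44, 0.03 and -0.22 and Fcc03386 at 0.41, while Fcc03091 ranged from 0.19 to 0.42 and Fcc00031 reached -0.01 without replicate 4 of copper 4 and pH D. The isopenicillin N synthetase had a pH D against A difference of 0.95 ± 0.45. It ran from 0.61 without replicate 4 of copper 2 and pH D to 1.61 without replicate 3 of copper 1 and pH A. A beta-lactamase match (Fcc01834) had one of 0.08 ± 0.10. That probe was well above background in 13 of the 41 samples, with 3 of 9 at pH A and 2 of 9 at pH D. Of 4 beta-lactam genes, 0 passed the threshold over the list alone.

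More probes passed for slide, scanning day and dye than for soil. Among the used samples, 54 of 4199 probes passed for slide, 89 for scanning day and 235 for dye. Within each slide, with 9 to 11 used samples and 1 to 3 residual degrees of freedom, 0 probes passed for copper or for pH. Within each slide with all 16 samples and 8 residual degrees of freedom, 0 probes passed as well, and the pH D against A contrast had 72, 219, 406 and 64 probes at an unadjusted p under 0.05 on slides 1 to 4.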

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

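The tests of slide order and exchanged positions, of both explanations for Fcc01630, and of other splits for the copper and pH F tests, their end contrasts, the slopes at pH A, B and C and the slope difference were chosen after the results were seen.

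The deposited value table differs from the scanner files in which array belongs to which sample. Every table array matched the scanner array at the same position of the next slide, with a lowest r of 0.966 across probes. An exchange of samples between array positions is argued against, since 32 of 32 table arrays matched a scanner array at the same position. A candidate explanation is that the table holds the slides in the order in which they were scanned, as 4 of 4 table slides matched the slide at that place in the scanning order. Whether the table or the scanner files carry the wrong slide number cannot be told apart, because samples of 1 group were not more alike in either pairing (permutation p = 0.0761 with the data moved by 1 slide, adjusted p = 0.304, with a difference of -0.0483 in mean r that points away from likeness). No biological explanation was tested.

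The value table in its own pairing gave 3 probes in the copper F test (limma, 3 of 4199), where the scanner files gave 0. These probes were chosen after their values were seen. The cellulase Fcc05266 was at 12.31 ± 0.86 (SD, n = 13), 11.2 ± 0.92 (SD, n = 8), 12.21 ± 0.66 (SD, n = 11) and 11.57 ± 0.70 (SD, n = 9) at copper levels 1 to 4 (adjusted p = 0.00147). The level 4 against 1 difference was -1.18 ± 0.29 (SE) in the table, 0.10 ± 0.35 in the scanner files and -0.81 ± 0.31 in the scanner files moved by 1 slide. Probes Fcc04150 (adjusted p = 0.00276) and Fcc00327 (adjusted p = 0.00935) have no protein match.

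Fcc01630 differed in its copper slope between pH levels (interaction, limma adjusted p = 0.000885). A single sample is a candidate explanation, since the log2 slope per copper level at pH D was 0.79 ± 0.14 (SE) with all used samples and 0.11 without replicate 4 of copper 4 and pH D. That was the used sample of its group, so leaving it out also takes copper 4 from pH D. The fall of the slope alone therefore cannot tell a single sample from an effect of copper. Soil copper at the highest pH is argued against as the whole cause, since 3 of the 4 samples of that group lay below the median of the other pH D samples. What set that sample apart stays open. The next highest value of the probe over the 64 samples was 7.83, against 9.88 in that sample and a median of 6.56.

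Splits of the used samples into groups of the same sizes were drawn 100 times, the real split included, and refitted. A real count of 0 is reached by every split, 100 of 100, so the splits decide nothing for such a count. This holds for the copper F test (highest other 5), copper 4 against 1 (highest other 4), the pH F test (highest other 80), pH D against A (highest other 1), the slopes at pH A (highest other 510), B (0) and C (0), and the slope difference (highest other 71). The real split of the interaction gave 1 probe, with 54 splits as large (highest other 378), and the slope at pH D 1 probe, with 21 as large (highest other 24). Chance could not be excluded for these counts, nor for the list counts, with 35 splits as large for copper (real 1, highest other 7) and 8 for pH (real 4, highest other 7). Splits with many times the real calls, up to 378 for the interaction, point to a structure of the samples, whose source was not tested.

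The number of probes with a small unadjusted p in the pH D against A contrast was 687, and 2 of 100 splits gave as many (highest other 778). Taken alone this share excludes chance at 5%, but of 10 unadjusted counts tested in this way it was the 1 under 5%, and with all 64 samples the number was 345. The same contrast in the value table paired as the scanner files gave 215 probes past the threshold, with 2 of 100 splits as large (highest other 745). For its unadjusted count 3 splits were as large. For the other counts of that version it was 13 (pH F test), 15 (pH F test, unadjusted) and 14 (pH lists). That version was chosen after the data were seen and holds the same arrays and samples, so it is no independent support for the 687 probes.

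Samples far from the others of their group were sought among 275 sets of 4 used samples (55 genes in 5 groups), and 14 were found. Chance gives about 1 in 20 sets, so 14 is about the number that chance alone would give. The sets are listed for completeness. Of the genes below, Fcc01758, Fcc00755 and Fcc04961 were well above background in 8, 18 and 26 of the 41 samples. At copper 3 and pH B, replicate 2 stood apart for 4 genes, with log2 values of 8.46 for the penicillin precursor synthetase Fcc00170 (others 6.65 on average), 12.62 for lipidosin Fcc00031 (others 12.31), 10.43 for Fcc01312 (others 9.88) and 8.22 for the glutathione transferase Fcc06274 (others 8.01). Replicate 1 of that group was at 7.45 for Fcc04988 (others 6.92). At copper 1 and pH D, replicate 4 was at 7.95 for Fcc00170 (others 6.83) and 13.06 for the maltase-glucoamylase Fcc00152 (others 13.66), and replicate 3 at 6.50 for Fcc01758 (others 6.19) and 6.59 for ferritin Fcc04961 (others 6.43). At copper 1 and pH B, replicate 2 was at 9.92 for Fcc03386 (others 9.51) and replicate 1 at 8.71 for the cytochrome P450 Fcc00266 (others 7.61). At copper 4 and pH C, replicate 4 was at 14.97 for the myosin light chain Fcc00218 (others 15.38) and replicate 1 at 6.87 for superoxide dismutase Fcc00755 (others 6.29). Replicate 4 of copper 1 and pH C was at 15.91 for ribosomal protein L44e Fcc03365 (others 15.45).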

How the results depend on the processing

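The tests with the data moved by 1 slide, without the groups of 1 used sample and with the value table paired as the scanner files were chosen after the data were seen. Signal over background limited the fits to 4199 of 5069 probes. Of 63 values of named genes, all 63 kept their direction without background subtraction, with the scanner software's processed signals, with quantile normalization, with and without loess, with no filter on dim probes, and with trend and robust variance. The copper F test and copper 4 against 1 stayed at 0 probes with scanner data in every setting that kept the files' pairing. Linear trends over the levels gave 0 for copper (73 unadjusted) and 0 for pH (419 unadjusted, limma). The muscle list had too few genes for a value with the filter at 75%. The cause of the differences given here was not tested, except where fewer samples or probes were used.

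In the value table with its own pairing, 20 of 63 named values kept their direction and 43 turned, with 3 in the copper F test, 0 in the slope at pH D, 4 of the copper lists and 2 of the pH lists past the threshold. None of these lists passed with an estimated correlation. Turned list means were -0.215 for carbohydrate digestion (pH), -0.148 for cytochrome P450 (copper), -0.147 for cytochrome P450 (pH), -0.171 for cytosolic ribosomal proteins (pH) and -0.212 for muscle structure (pH). Slope differences turned for Fcc00031 at 0.38, Fcc00057 at -0.05, Fcc00170 at -0.21, Fcc01630 at -0.36, Fcc01758 at -0.35 and Fcc05644 at -0.14. pH signs turned for Fcc00048 at -0.05, Fcc00050 at -0.27, Fcc00152 at -0.08, Fcc00218 at -0.12, Fcc00266 at -0.19, Fcc00353 at -0.27, Fcc00529 at -0.32, Fcc01480 at -0.28 and Fcc01651 at -0.17. Also turned were Fcc02198 at -0.14, Fcc02219 at -0.33, Fcc02249 at -0.16, Fcc02522 at -0.18, Fcc02595 at -0.05, Fcc03365 at -0.23, Fcc04059 at -0.22, Fcc04074 at -0.13 and Fcc04248 at -0.22. Turned as well were Fcc04469 at 0.1, Fcc05061 at -0.48, Fcc05148 at -0.22, Fcc05618 at -0.23 and Fcc06274 at -0.42. Copper signs turned for Fcc00218 at -0.14, Fcc00266 at -0.25, Fcc00390 at -0.45, Fcc00677 at 0.3, Fcc00755 at -0.16, Fcc01651 at -0.06, Fcc02070 at -0.01, Fcc02595 at -0.34 and Fcc02719 at -0.19. Also turned were Fcc03142 at -0.05, Fcc04079 at 0.03, Fcc04248 at -0.21 and Fcc04988 at -0.02. The pH D slope turned for Fcc01630 at -0.04.

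With the value table paired as the scanner files, 57 of 63 kept their direction, with 10 in the interaction F test, 2 in the slope difference, 215 in the pH D against A contrast and 2 in the pH F test past the threshold. In that setting, slope difference signs turned for Fcc00031 at 0.04. pH signs turned for Fcc03091 at 0.01 and Fcc03280 at 0.09. Copper signs turned for Fcc04079 at 0.05, Fcc04514 at 0.05 and Fcc05933 at 0.11. Moved by 2 slides instead, a pairing with no support in the files, the table gave 91 probes in the interaction F test.

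With the scanner data moved by 1 slide, to the pairing of the table, the lists that passed lay lower at copper 4, with 0 in the interaction F test, 0 in the slope at pH D, 3 of the copper lists and 1 of the pH lists past the threshold. With an estimated correlation these lists had an adjusted p = 0.412 (copper) and an adjusted p = 0.751 (pH), and 0 passed. Turned list means were -0.047 for carbohydrate digestion (pH), -0.048 for cytochrome P450 (copper), -0.002 for cytochrome P450 (pH) and -0.122 for muscle structure (pH). The same move was made with all 64 samples, with 0 in the interaction F test, 0 in the slope at pH D, 3 of the copper lists and 5 of the pH lists past the threshold. With an estimated correlation 0 of these lists passed. For copper the adjusted p = 0.318 for carbohydrate digestion, 0.52 for ribosomal proteins and 0.175 for muscle. The pH lists, each with an adjusted p of 0.046, were ribosomal proteins, muscle, heat shock and phase II, lower at pH D, and mitochondrial respiration, higher. With an estimated correlation the adjusted p = 0.607 for ribosomal proteins, 0.552 for phase II and 0.301 for the other 3. Turned list means were -0.119 for carbohydrate digestion (pH), -0.02 for cytochrome P450 (copper), -0.054 for cytochrome P450 (pH), -0.046 for cytosolic ribosomal proteins (pH) and -0.161 for muscle structure (pH). The difference between used and not used samples in the share of spots well above background turned from -0.5 to 1.6 percentage points (permutation p = 0.101).

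With all 64 samples, 52 of the 63 named values kept their direction, with 0 in the interaction F test, 0 in the slope at pH D, 0 of the copper lists and 1 of the pH lists past the threshold. In that setting, copper signs turned for Fcc00218 at -0.04, Fcc00390 at -0.09, Fcc00677 at 0.25, Fcc00755 at 0, Fcc01918 at -0.04, Fcc02070 at -0.01, Fcc02595 at -0.06, Fcc02719 at -0.12 and Fcc04079 at 0.06. pH signs turned for Fcc00218 at -0.03 and Fcc03280 at 0.06. With array weights added to all 64 samples, 49 of 63 kept their direction, with 0 in the interaction F test past the threshold. In that setting, copper signs turned for Fcc00218 at -0.04, Fcc00390 at -0.14, Fcc00677 at 0.26, Fcc00755 at -0.04, Fcc02070 at -0.02, Fcc02595 at -0.14, Fcc02719 at -0.14, Fcc03343 at 0.02 and Fcc04079 at 0.06. pH signs turned for Fcc00218 at -0.11, Fcc01834 at -0.01, Fcc03091 at 0.05, Fcc03280 at 0.06 and Fcc05061 at -0.08.

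With slide as a block, 61 of 63 kept their direction, with 0 in the slope at pH D past the threshold. In that setting, pH signs turned for Fcc03280 at 0.02. Copper signs turned for Fcc04079 at 0. With equal weights for the 16 groups, 48 of 52 kept their direction. In that setting, copper signs turned for Fcc00266 at -0.01, Fcc00677 at 0.13 and Fcc02719 at -0.05. pH signs turned for Fcc03280 at 0.02. Without the array block, 62 of 63 kept their direction, with 1 of the pH lists past the threshold. In that setting, copper signs turned for Fcc00677 at 0.04. Without the dye term, 62 of 63 kept their direction, with 1 in the slope difference past the threshold. In that setting, pH signs turned for Fcc03280 at 0.02. Slide shifted single probes (54 passed). Deviations of samples from their group means correlated at 0.0427 on average within slides, against -0.0152 between different slides and groups. A correlation of 0.1 was exceeded by 42.2% of pairs within a slide and 32.2% of pairs from different slides and groups. The slide block gave 5 pH lists, with phase II detoxification added (adjusted p = 0.0463, and adjusted p = 0.477 with an estimated correlation), and, apart from the slope at pH D, changed no other count.

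An estimated correlation between genes ended the list calls, with 0 of the copper lists and 0 of the pH lists past the threshold. The scanner software's processed signals ended calls of a single transcript and list, with 0 in the interaction F test, 0 in the slope at pH D and 0 of the copper lists past the threshold. Another result came without background subtraction, with 1 in the slope difference and 1 of the pH lists past the threshold. Quantile normalization was also run without loess, with 1 in the slope difference past the threshold. Without a filter, 5069 probes were tested, with 2 in the interaction F test and 2 in the slope at pH D past the threshold. The filter at 75% of samples tested 3748 probes, with 0 in the interaction F test, 0 in the slope at pH D, 0 of the copper lists and 1 of the pH lists past the threshold. Fewer samples were fitted without the groups of 1 used sample, with 0 in the interaction F test past the threshold.

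Leaving out each of the 41 samples in turn can leave a group with 1 or 0 samples, and a lone sample is then taken to vary like those of other groups. The interaction count ran from 0 to 140, with 2 without copper 3 pH A replicate 1, 140 without copper 2 pH A replicate 1, 2 without copper 2 pH A replicate 2, 2 without copper 2 pH D replicate 2, 5 without copper 1 pH B replicate 4, 0 without copper 4 pH D replicate 4 and 9 without copper 2 pH D replicate 4. That of pH D against A ran from 0 to 2, with 1 without copper 2 pH A replicate 1 and 2 without copper 4 pH A replicate 1. The slope at pH D ran from 0 to 1, with 0 without copper 4 pH D replicate 4. The slope difference ran from 0 to 1, with 1 without copper 2 pH A replicate 1 and 1 without copper 3 pH D replicate 2. Copper lists ran from 0 to 3, with 0 without copper 4 pH C replicate 1, 0 without copper 4 pH A replicate 1, 2 without copper 4 pH C replicate 2, 0 without copper 1 pH C replicate 2, 0 without copper 4 pH C replicate 3 and 3 without copper 4 pH C replicate 4. For pH lists the count ran from 1 to 7, with 1 without copper 4 pH C replicate 1, 1 without copper 3 pH A replicate 1, 1 without copper 1 pH D replicate 1, 1 without copper 3 pH D replicate 2, 7 without copper 2 pH A replicate 2 and 1 without copper 1 pH D replicate 3.

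Values over these fits ran from 0.111 to 0.235 for cytochrome P450 (copper list mean), 0.224 to 0.297 for cytochrome P450 (pH list mean), 0.235 to 0.365 for carbohydrate digestion (pH list mean) and 0.234 to 0.311 for muscle structure (pH list mean). Other ranges were 0.5 to 0.66 for Fcc02219 (pH D against A), -0.11 to 0.03 for Fcc03091 (pH D against A), -0.01 to 0.44 for Fcc01312 (the slope difference) and -0.04 to 0.05 for Fcc04079 (copper 4 against 1). Further ones were -0.01 to 0.11 for Fcc01918 (copper 4 against 1), -0.14 to 0.08 for Fcc00677 (copper 4 against 1), -0.14 to 0.03 for Fcc04514 (copper 4 against 1) and -0.08 to 0.08 for Fcc03280 (pH D against A). The last were 0 to 0.14 for Fcc01834 (pH D against A), 0.11 to 1.03 for Fcc01630 (the slope at pH D) and 0.35 to 1.26 for Fcc01630 (the slope difference).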

Other observations

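The tests of soil group and moulting stage below, and the genes and list pairs named, were chosen after the values were seen.

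Across all 64 samples, whatever their soil, several gene lists varied together. A list's score in a sample was the mean of its genes' standardized deviations. For each gene, slide and dye were fitted to the log2 values, and what was left was divided by its SD. Phase II detoxification and oxidative stress defence correlated at r = 0.841 (rho = 0.827) over samples, each with a permutation p of 1e-05, the smallest that the resamples can give (adjusted p = 3.18e-05 for r over 105 list pairs), and at 0.83 without the 2 farthest samples. Cytochrome P450 genes went with phase II detoxification at r = 0.855 (rho = 0.847) and with carbohydrate digestion at r = 0.824 (rho = 0.802), and oxidative stress defence with the bacterial matches at r = 0.864 (rho = 0.83), with the same permutation p and adjusted p. Of the 105 pairs, 73 had an adjusted p under 0.05, 67 of them positive and 6 negative. Lists of random genes vary together as well. For 1000 random list pairs, with the sizes and brightness of phase II detoxification and oxidative stress defence, the median r was 0.042. The upper limit of their central 95% was 0.571, so a pair can pass the permutation test with an r that random lists also reach. Over all slides, heat shock proteins and ABC transporters did not follow phase II detoxification, at r = 0.0992 (rho = 0.188, permutation p = 0.435 and 0.136) and r = -0.127 (rho = -0.0631, permutation p = 0.317 and 0.616). For heat shock proteins that r ran from -0.232 on slide 2 to 0.697 on slide 1. ABC transporters and oxidative stress defence had r = -0.421 (rho = -0.31, permutation p = 0.00055 and 0.0132), and 0.0354 on slide 3. The first principal component held 26.8% of the variance left after slide and dye were fitted.

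Technical explanations for these shared scores were weighed on phase II detoxification and oxidative stress defence. Brightness of the channel stays open. The phase II score correlated with the log2 median signal at r = 0.0238 (rho = 0.0345, permutation p = 0.85 and 0.786). Dye had been fitted out of the score. The median signals of the dyes did not overlap, at 109 to 337 in Cy3 and 391 to 1310 in Cy5. The r was therefore held low in advance and cannot decide. Array quality is argued against as the whole cause, as r was 0.864 in differences between the samples of an array. Slide had been fitted out of the scores, so they cannot test it as a cause. The r of at least 0.773 within each slide shows only that the scores went together on every slide. None of the 1000 random list pairs had an r as high as the real pair, a share of 0.0999% with the real pair counted, which argues against any 2 lists of these sizes doing the same. Soil group is argued against as the whole cause, as r was 0.875 within soil groups, and 0.848 with the data moved by 1 slide. A part played by soil stays open (permutation p = 0.909 for the phase II score over the 16 groups, 0.927 with the data moved). Moulting stage, a hypothesis, stays open too, and the phase II and cuticle scores had r = 0.396 (rho = 0.432, permutation p = 0.00118 and 0.00031). That r lies below 0.571, the upper limit of the random list pairs above, which had other sizes. Its p therefore does not weigh for moulting. A state of the animals that the labels do not record may be behind the shared scores, and this was not tested. Technical differences between single samples, which remain within arrays and slides, were not tested either.

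Among the named genes that varied most over the 64 samples, some correlated with one another. SDs and correlations here are of the log2 values left after slide and dye were fitted. The median SD over genes was 0.23 log2 units. Cuticle protein 8 (Fcc03188) had an SD of 1.28, a serine proteinase (Fcc04942) 1.09, the antimicrobial peptide Alo2 (Fcc05968) 1.01, isopenicillin N synthetase (Fcc00057) 0.98, a monooxygenase (Fcc00415) 0.95 and lipase H (Fcc03348) 0.91. The proteinase and the lipase correlated at r = 0.921 (rho = 0.905) over samples, and at 0.906 without the 2 farthest samples. The penicillin pathway genes Fcc00057 and Fcc00170 correlated at r = 0.912 (rho = 0.769), and at 0.856 without those samples. Cuticle protein 8 went with the monooxygenase at r = 0.814 (rho = 0.84, and 0.788 without the 2 farthest) and with cuticle protein 2 (Fcc04335) at r = 0.812 (rho = 0.796, and 0.814). Each of these r and rho had a permutation p of 1e-05, the smallest possible, with an adjusted p of 0.000127 for r over 190 pairs, and the lowest r within a slide was 0.896, 0.773, 0.702 and 0.656 for the 4 pairs in this order.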
